A study of Mus musculus with 6 samples.

How the data were processed

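The series holds droplet single-cell RNA libraries of mouse bone marrow cells, made with 3′ chemistry on the MobiDrop MobiNova-100 instrument, per the labels. Of the 6 libraries, 4 came from Vav1-cre iMOS mice aged 12 months and were named for the genotype (Bcl11a-WT or Bcl11a-MUT) and for the sorted fraction (T1 or T2). The labels do not say what T1, T2 or MUT stand for. The other 2 libraries came from cells of C57BL/6J mice aged 8 to 12 weeks that were cultured for 48 h with OVA or with its IC form (OVA-IC), per the labels. The series text gives the cultured cells as LSK, while each sample's own label gives LSK and LK. LSK are lineage-negative, Sca-1-positive, c-Kit-positive cells, the bone marrow fraction that holds the stem cells, and LK are lineage-negative, c-Kit-positive progenitors.

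For each library the authors deposited a matrix of whole-number UMI counts, with 32287 genes and the barcodes kept by their own filter. The genome build was mm10, per the submitters' processing notes. The aligner, the counting tool and the rule that chose barcodes are not given in the sources used here. The deposited counts contain 2 reporter sequences, Td and GFP, besides the mouse genes, and no barcode had fewer than 500 UMIs. No normalization had been applied to the counts, which summed to a different total in each library. The counts carry no statement on strand or on reads shared between genes, so pseudogenes, paralogs and antisense genes are uncertain where they are named.

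Cells were kept with at least 1000 UMIs, at least 500 genes and at most 10% of UMIs from mitochondrially encoded genes. This left 10742 cells in MUT T1, 15634 in MUT T2, 12982 in WT T1, 21493 in WT T2, 13229 in IC and 12555 in OVA. Doublets were called per library with Scrublet in scanpy, at an expected rate of 6%. The caller marked 1, 3, 2 and 0 cells of MUT T1, MUT T2, WT T1 and WT T2. A caller that marks under 0.5% of over 5000 cells was taken as not having worked, so no cell was removed from these 4 libraries and doublets remain in them. In IC and OVA the 144 and 205 called cells (1.08% and 1.61%) were removed.

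The 4 iMOS libraries were clustered together, and IC with OVA, without batch integration. Counts were scaled to 10000 UMIs per cell and log-transformed, 2000 variable genes were taken without sex-linked genes, Bcl11a, mitochondrial, ribosomal and haemoglobin genes, and 30 principal components, 15 neighbours and Leiden clustering at resolution 1 followed. This gave 23 iMOS clusters and 19 culture clusters. A cluster took the name of 1 of 15 classes, written as X-like, when at least 3 markers of the class were detected in at least 10% of its cells at 1.5 times the level of the other cells, with a mean log2 fold of at least 0.25 over the class's markers. It stayed unnamed when its leading 10 genes held more markers of another class. It also stayed unnamed when these genes held no marker of its class and either under 50% of the class's markers reached that level or 3 times its median UMI count lay under the library median. The markers had been fixed beforehand, but this naming rule and its bounds were set after the clusters, their leading genes and their shares per library had been seen. By hand, after the clusters were seen, 1 iMOS cluster led by Trbc1 and Themis and 1 culture cluster led by H2-Aa and Nfil3 were left unnamed, since their other leading genes went against the lymphoid-primed and dendritic names that the rule gave. Bcl11a and the reporters Td and GFP were kept out of clustering. Outside the sets named above, other genes that differed between libraries were not.

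Levels are UMIs summed over the cells of a library and divided by their total, given as CPM, over all cells and over each class with at least 100 cells in both libraries. Each level has an exact Poisson 95% interval and each share of cells an exact Clopper-Pearson 95% interval. A count of 0 is given with the limit that 3 counts would set. Intervals and limits cover counting error only. The ratio of 2 libraries is log2((CPM + 5)/(CPM + 5)), which understates differences of low genes. Its interval is that of the plain ratio of the 2 levels, without the 5 added, so it need not centre on the value given. Each group has 1 library, so there was no test, p-value or standard error, and no check against replicates, and counts of genes past 1.5-fold describe size alone. Animals behind each library are not given in the sources used here. A further 31 gene lists covering blood lineages, other cell types, signalling, cell cycle and metabolism were described by the median log2 ratio of members with a mean of at least 5 CPM. Each median is given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins, which describes these libraries only. Members at least 1.5-fold higher or lower were counted. Lists with under 5 measured members are not described by a median. That minimum was set after a first set of medians had been seen, as was the size of 0.2 on the log2 scale from which a list median was taken to have a direction.

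The genes named were chosen by a rule of size: in each comparison the 6 genes with the highest and the 6 with the lowest ratio over all cells, and over HSC/MPP-like cells for IC against OVA and for WT against MUT. They needed at least 20 CPM in the higher library and 30 UMIs in both together. Unnamed gene models, mitochondrial, ribosomal and receptor segment genes and the genes of a sex-linked list were left out of this ranking. That list, also used for clustering, does not hold every X-linked gene and lacks Mid1. Always listed were Bcl11a, Fcgr2b, Fcgr3, Fcer1g, Procr, Hlf, Mecom, Cd34, Flt3, Mpo, Gata1, Cdk6, Cdkn1a, Cdkn1c and Mki67, and up to 2 members each way of each list described. The 5 comparisons, the groups, the cell filters, the clustering, the markers, the lists, this rule and most alternatives were set before the data were examined. Genes or clusters outside the rule are named as chosen after their values were seen. List medians by cluster within the HSC/MPP-like class were added after the class values had been seen. Positions are from the GENCODE vM21 annotation of GRCm38, the assembly that mm10 names.

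The alternatives were stricter or no filters on cells, called doublets kept in IC and OVA, Leiden resolutions 0.5 and 2, clustering without cell cycle and immediate early genes, edgeR's TMM factors, totals without mitochondrial, ribosomal and haemoglobin genes, the mean of per-cell CPM, a pseudocount of 1, cells thinned to 2000 UMIs, no floor on expression, and levels standardised to the same cluster shares. After the data were seen, 6 settings were added, as 10 alternatives when counted by kind of result. Each was run in every comparison it applied to, so they number more when counted by comparison. They removed the 6% of cells with the highest doublet scores, counted a Cd74-led cluster or the WT T1 cluster led by Pde3b and Pgr as HSC/MPP-like, left low-depth clusters or clusters of 1 library out of the denominator, or read levels in HSC/MPP-like cells in place of all cells. For results within a class, the run with no filter on cells was left out, and the stricter filter kept the class names of the main clustering.

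The calculation was tested on Poisson counts simulated for the library sums of WT against MUT in T1, over 6869 genes. The interval assumes the same Poisson error. Its coverage thus checks the arithmetic alone, not the spread between cells or libraries. Simulated 1.5-fold, 2-fold and 4-fold differences were recovered in the right direction in 100% of 68, 63 and 69 genes, with median sizes of 0.52, 0.91 and 1.81 on the log2 scale. The interval of the ratio covered the true value in 88.2%, 96.8% and 88.4% of them, and in 95.0% of 6669 unchanged genes. A check over 20 draws, added after those shares were seen, gave 94.5%, 95.6%, 96.6% and 95.1%. A simulated list of 20 genes raised 2-fold lay at percentile 100, and 20 unchanged genes at 50.7.

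The total per library ranged from 112008324 to 159482976 UMIs over all barcodes and from 107004635 to 154112746 in the cells kept. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16. IC was sequenced on lane 4 and OVA on lane 6, per the sample titles, so the lane cannot be told apart from the treatment. All 4 iMOS libraries share lane 6.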

Results

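Bone marrow stem and progenitor cells were profiled in 6 single-cell libraries, with 1 library in each of 6 groups. In the first experiment, cells of young C57BL/6J mice, LSK per the series text and LSK and LK per the sample labels, were held for 48 h with OVA or with OVA-IC (the IC library), to learn what activation of the Fc gamma receptor signal does to haematopoietic stem cells (HSCs). In the second, T1 and T2 cells were sorted from Vav1-cre iMOS mice of 12 months that carried Bcl11a-WT or Bcl11a-MUT. Its stated purpose was the role of Bcl11a within HSCs and the effect of Bcl11a overexpression on neighbouring wild-type HSCs. Bcl11a encodes a zinc finger repressor known for silencing fetal globin genes and for its part in lymphoid development. The cells kept numbered 12982 in the WT T1 library, 21493 in WT T2, 10742 in MUT T1, 15634 in MUT T2, 13229 in IC and 12555 in OVA. Their median depth was 8161, 5537, 8767, 6822, 10966 and 11355 UMIs per cell in the same order. With 1 library per group no difference could be set against the spread between animals or cultures, and all intervals below cover counting error only.

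The reporter transcripts and Bcl11a were read first, as a check of the labels. GFP was counted in both T1 libraries, at 5.29 CPM (4.89 to 5.71) in WT and 10.4 CPM (9.745 to 10.97) in MUT, and Td in both T2 libraries, at 12.0 CPM (11.5 to 12.6) in WT and 22.9 CPM (22.1 to 23.8) in MUT. GFP was near 0 in T2, with 1 UMI in WT and 3 in MUT, and Td was near 0 in T1, with 2 UMIs in WT and 0 in MUT, which allows up to 0.028 CPM. Neither reporter was seen in IC or OVA, which allows up to 0.0205 and 0.0201 CPM. Each reporter thus marked 1 sorted fraction, and both stood at a higher level in the MUT libraries. The iMOS libraries held Xist at 1636 to 1724 CPM and no UMI of Eif2s3y, which allows up to 0.0195 to 0.028 CPM. IC and OVA held Eif2s3y at 122 and 132 CPM and almost no Xist. Ddx3y, another Y-linked gene, was counted in the iMOS libraries as well, at 8.855 to 18.82 CPM, against 213.1 in IC and 204 in OVA. Apart from this gene, the iMOS cells carried female and the cultured cells male transcripts.

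**Figure D1:**
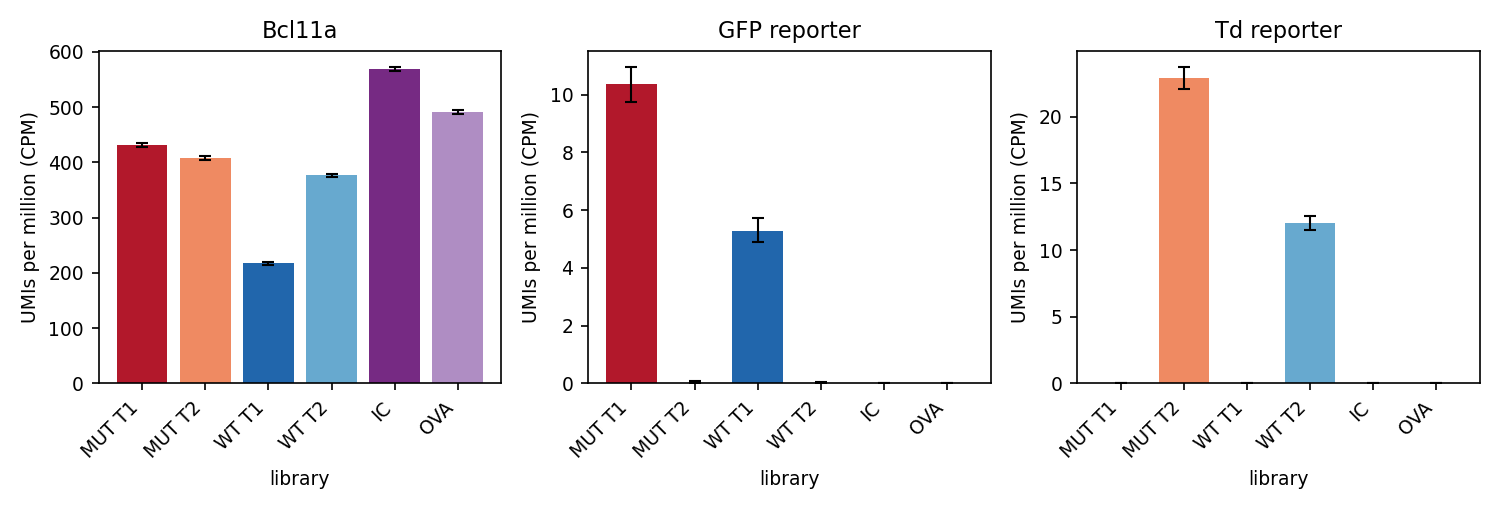
Levels of Bcl11a, GFP and Td in CPM over all cells of each of the 6 libraries, with exact Poisson 95% intervals that cover counting error only. Bcl11a was at 218 CPM in WT T1 and between 377 and 432 CPM in the other 3 iMOS libraries, GFP was read in T1 and Td in T2.

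Bcl11a (chromosome 11, 24078056 to 24174123, plus strand) was at 431.8 CPM (427.9 to 435.8) in MUT T1, 408.1 (404.5 to 411.6) in MUT T2, 376.5 (373.5 to 379.6) in WT T2 and 217.7 (215.1 to 220.4) in WT T1. The labels do not say which library should hold more of it, and a transgene with another 3′ end need not be counted under the gene, so its level does not settle which cells overexpressed it. In HSC/MPP-like cells it was at 373 CPM (361 to 386) in WT T1, 467 (458 to 476) in WT T2, 494 (485 to 503) in MUT T2 and 530 (521 to 540) in MUT T1. The lymphoid-primed-like cells held 352 CPM in WT T1 against 616 in MUT T1, with 567 in WT T2 and 610 in MUT T2. Erythroid progenitor-like cells held 489 CPM in WT T1 against 584 in MUT T1, and neutrophil progenitor-like cells from 93.9 to 122 CPM over the 4 libraries. The last class pools cluster 9 with cluster 12, which has a low depth. In cluster 9 Bcl11a was at 72.1 CPM in WT T1, 119 in WT T2, 114 in MUT T1 and 109 in MUT T2. In cluster 12 it was at 177, 161, 183 and 171 CPM in the same order. Both clusters were chosen after the class values had been seen.

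Cells stimulated with OVA-IC were compared with cells given OVA to see what Fc gamma receptor activation did. IC cells had higher levels of Mt1, Mt2, Hmox1 and 5 of 21 NF-kB and inflammatory genes, and lower levels of Fos and 3 of 13 lymphoid genes, counted from 1.5-fold. Mt2, which encodes a metal-binding metallothionein, was highest by ratio at 66.2 CPM (64.9 to 67.6) in IC against 14.4 (13.75 to 14.97) in OVA, 3.68-fold. Its relative Mt1 was 2.22-fold higher, at 294 against 130 CPM. Hmox1, the enzyme that breaks down haem, was at 98.6 CPM (97.0 to 100.3) against 45 (43.9 to 46.1), 2.07-fold higher. The transcription factor gene Fos was at 121.5 CPM (119.7 to 123.3) in IC against 245.8 (243.3 to 248.4) in OVA, 1.98-fold lower.

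The list of NF-kB and inflammatory genes stood apart. Its 21 measured members had a median log2 ratio of 0.43, at percentile 100 of random lists, with 5 members at least 1.5-fold higher in IC and 0 lower. Ptgs2, which encodes the inducible prostaglandin synthase, was at 26.7 CPM (25.8 to 27.5) in IC and 11.1 (10.6 to 11.7) in OVA. Tnf, the gene of an inflammatory cytokine, was at 25.4 CPM (24.6 to 26.2) and 12.3 (11.8 to 12.9). The lowest members were Rel, at 114 CPM in IC and 125 in OVA, and Sod2, at 97.8 and 103 CPM. Bcl2a1b, a survival gene of the Bcl2 family known to be induced by NF-kB, was 2.43-fold higher in IC, while Bcl2 itself was at 166 CPM against 246 in OVA.

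**Figure D2:**
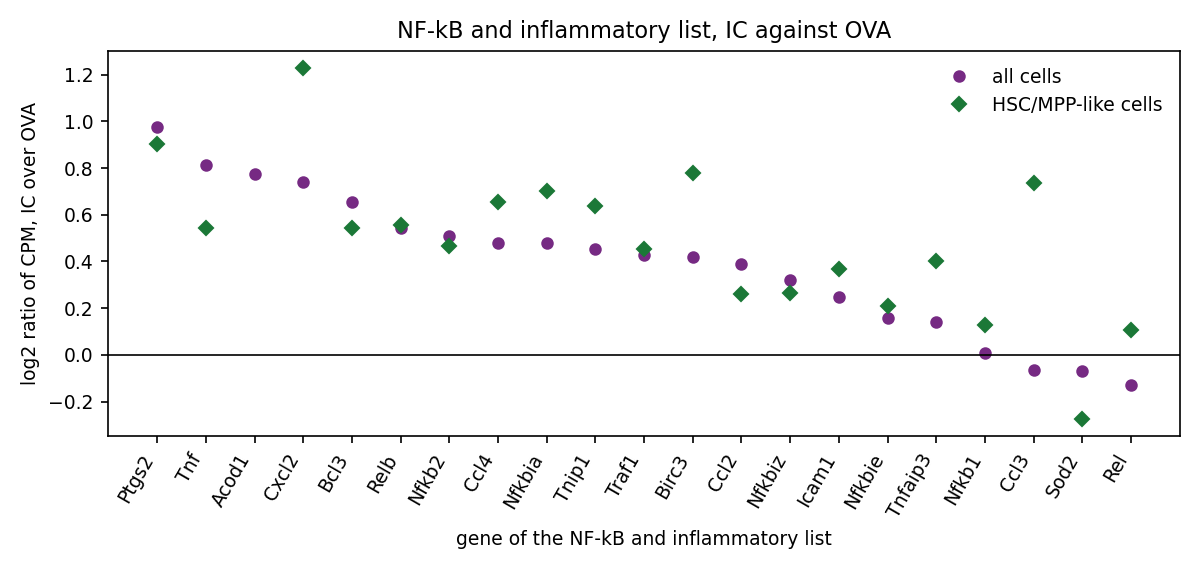
Log2 ratio of IC to OVA for each measured member of the NF-kB and inflammatory list, over all cells and over HSC/MPP-like cells. Most members lie above 0, with Ptgs2 at 0.97 over all cells and 0.90 in HSC/MPP-like cells, and Rel, Sod2 and Ccl3 lie below it over all cells.

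Genes of the Fc gamma receptor itself went apart. Fcgr2b, the inhibitory receptor (chromosome 1, 170958617 to 170976547, minus strand), was at 57.4 CPM (56.1 to 58.6) in IC against 40.2 (39.2 to 41.2) in OVA. Fcgr3, an activating receptor (chromosome 1, 171051174 to 171064935, minus strand), was at 3.33 CPM (3.04 to 3.63) against 7.92 (7.48 to 8.39). Fcer1g, the signalling chain shared by activating receptors, was at 219 CPM (217 to 222) against 235 (232 to 237). In HSC/MPP-like cells Fcgr2b and Fcgr3 were near the floor, at 5.84 against 3.89 CPM and 0.48 against 0.83 CPM, and Fcer1g was equal within counting error at 87.0 CPM (84.1 to 90.1) against 86.6 (83.7 to 89.7). The 23 measured genes of the receptor and its signalling had a median of −0.08, at percentile 10.9, with 0 members higher and 1 lower by 1.5-fold.

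Other genes with the highest ratios in IC were Sgcz (2.97-fold), Cp, which encodes the copper carrier ceruloplasmin (2.77-fold), Spp1, the gene of osteopontin (2.497-fold), and Hbb-bt, an adult beta globin gene (2.38-fold). At the other end were Apba1 (2.05-fold lower), Pgr, the progesterone receptor gene (1.98-fold), Cmah (1.98-fold), and the cholesterol exporter genes Abcg1 and Abca1 (1.97-fold and 1.95-fold). Ly6a, which encodes the Sca-1 antigen used in the sort, was at 280 CPM in IC and 175 in OVA. Among genes with a direct part in stem cell identity, Hlf was at 334 CPM against 407, Mecom at 421 against 453, Cd34 at 169 against 197 and Procr at 21.8 against 17.8.

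Lineage lists were described over all cells. The lymphoid list had a median of −0.21 over 13 members, at percentile 0.03, with 3 lower by 1.5-fold, among them Dntt, the terminal transferase gene (59.9 against 109 CPM), and Il7r, the interleukin 7 receptor gene (46.9 against 77.9 CPM). The HSC list had a median of −0.16 over 21 members (percentile 0.02, 2 higher and 0 lower), the basophil, mast and eosinophil list −0.22 over 7 (percentile 0.1), the megakaryocyte list −0.15 over 10 (percentile 0.83) and the erythroid list −0.07 over 7 (percentile 28.7). Monocyte and dendritic genes split, with Cd74 at 99.1 against 60.8 CPM and the dendritic and monocyte regulator Irf8 at 132 against 240 CPM, and their median was 0.04 over 18. Mpo, the myeloperoxidase gene of early granulocytes, was at 105 CPM against 172, while the neutrophil progenitor list had a median of 0.07 over 11. The macrophage list had a median of 0.70 over 5 members (percentile 100), carried by Hmox1, Spic and the iron exporter gene Slc40a1, at 24.6 against 13.2 CPM, which also belong to haem and iron handling. Only 3 T and NK cell members, 4 mature B and plasma cell members and 3 stromal and endothelial members were measured.

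Of the lists on signalling and cell state, immediate early genes had a median of −0.14 over 18 members (percentile 0.24, 3 lower), with Egr1 at 79.9 against 135.5 CPM. Oxidative phosphorylation genes had a median of 0.18 over 38 and Myc and ribosome biogenesis genes 0.18 over 32, both at percentile 100, with 0 members of either at least 1.5-fold higher. The medians of the ribosomal protein, unfolded protein response, S phase, cholesterol synthesis and glycolysis lists were 0.11, 0.11, 0.05, 0.05 and 0.04. G2 and M phase genes stood at −0.12 (percentile 0.03) and cell cycle inhibitors at −0.21 (percentile 0.01), with Cdkn1a at 45.03 against 36.4 CPM, Cdk6 at 1010 against 1053 and Mki67 at 21.1 against 25.7. Interferon response, p53 target, apoptosis and mitochondrially encoded genes lay at 0.0007, −0.02, −0.04 and −0.08, and aged HSC and MHC class II genes at 0.04 and 0.06.

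HSC/MPP-like cells made up 24.98% (24.24 to 25.72) of IC and 22.42% (21.69 to 23.16) of OVA, a log2 ratio of shares of 0.16 (0.08 to 0.23). Within them, NF-kB genes had a median of 0.54 over 21 members (percentile 100), with 8 higher, among them Birc3, an inhibitor of cell death (132 against 74.6 CPM). Bcl11a was at 521 CPM (514 to 529) in IC and 400 (394 to 407) in OVA, but the 3 clusters of the class went apart, with 639 against 411 CPM in cluster 0, 433 against 422 in cluster 6 and 331 against 359 in cluster 8. Sgcz (3.46-fold), Mt2 (3.26-fold), Bcl2a1b (3.10-fold), Sorcs1 (2.91-fold), the chemokine gene Ccl5 (2.75-fold) and Spic, a regulator of iron-recycling macrophages (2.72-fold), led in IC. Fos (1.99-fold lower), the adhesion gene Ncam2 (1.95-fold), Rgcc (1.79-fold), Gem (1.75-fold), Pgr (1.67-fold) and Clnk (1.63-fold) were at the other end. The aged HSC list had a median of 0.09 over 20, with 4 higher, among them Fyb at 629 against 253 CPM, and medians of 0.25, 0.10 and 0.23 in clusters 0, 6 and 8. Sgcz and Ncam2 are also leading genes of the clusters that make up the class, and many HSC genes define it.

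The neutrophil progenitor-like share was 18.7% in IC and 20.5% in OVA, the monocyte progenitor-like share 9.86% and 15.6%, and the lymphoid-primed-like share 2.92% and 4.81%. Different clusters held the first 2 of these classes. Cluster 7, led by Ctsg and Fcgr2b, was 10.9% of IC and 1.77% of OVA, and cluster 1, led by Ccl9 and Pgr, 7.08% and 15.1%. Cluster 15, led by the mast cell gene Cpa3 but named neutrophil progenitor-like, was 0.79% and 3.59%. Elane, a marker of that class, was low in the class in both libraries, so the name is uncertain. Cluster 2, led by Wfdc17 and also by Apba1, was 5.49% and 12.9%, and cluster 12, led by Cxcl2, 4.37% and 2.68%. Because Fcgr2b, Pgr and Apba1 themselves differed between the libraries, these sizes may follow the libraries' expression as well as their cells, which was not tested. The HSC/MPP-like log2 ratio turned to −0.36 at Leiden resolution 2, and lane and treatment cannot be told apart.

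WT and MUT were compared in T1 cells, where the WT library had fewer cells of the HSC/MPP-like class and more granulocyte and monocyte transcripts. HSC/MPP-like cells made up 9.11% (8.62 to 9.61) of WT T1 and 22.8% (21.96 to 23.6) of MUT T1, 2.499-fold fewer, with a log2 ratio of −1.32 (−1.42 to −1.22). Neutrophil progenitor-like cells made up 16.2% (15.6 to 16.8) and 5.74%, of which cluster 9 was 4.90% and 4.31% and cluster 12, with a median depth of 0.1998 of the library median, 11.3% and 1.43%. S100a9 and S100a8 (chromosome 3, 90692632 to 90695721 and 90668978 to 90670035), the genes of the calprotectin subunits of neutrophils and monocytes, were 22.2-fold and 11.2-fold higher in WT. Bcl11a was 1.96-fold lower in WT, a log2 ratio of −0.97 (−1.01 to −0.97 without the added 5 CPM), and 1.42-fold lower within HSC/MPP-like cells. At equal cluster shares its log2 ratio was −0.49.

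S100a9 was at 440.5 CPM (436.8 to 444.3) in WT T1 and 15.1 (14.4 to 15.9) in MUT T1. Granule protein genes Camp and Ngp were at 92.5 against 2.75 CPM and 26.5 against 0.37 CPM, Dmkn was 8.20-fold and Ms4a6c 5.37-fold higher, and the monocyte antigen gene Ly6c2 was at 373 against 80.7 CPM. The neutrophil progenitor list had a median of 1.03 over 20 members (percentile 100, 14 higher and 0 lower) and the monocyte and dendritic list 1.03 over 20 (percentile 100, 16 higher). Basophil, mast and eosinophil genes had a median of 0.45 over 10, with Cpa3, a mast cell protease gene, at 140 against 63.7 CPM. At equal shares of the 16 clusters with at least 50 cells in both libraries the neutrophil progenitor median was −0.0068, but these hold 76.18% of WT T1 cells and leave out clusters 14 and 22, which carry many of the UMIs of these genes. Maturing neutrophil-like cells (cluster 22), a class of 60 cells that made up 0.462% (0.353 to 0.595) of WT T1 and 0% of MUT T1, which allows up to 0.0279%, held 92.5% of the Camp, 94.3% of the Ngp, 58.2% of the S100a9 and 39% of the S100a8 UMIs of WT T1. Cluster 14 held 63.8% of the Elane, 70.4% of the Ly6c2, 82.6% of the Dmkn and 34.9% of the S100a9 UMIs, and cluster 12 held 1.04 to 2.91% of the UMIs of these genes other than Ngp (0.933%). These counts per cluster were chosen after the values were seen. Cluster 14, led by Ly6c2, Dmkn and Elane, was 14.2% of WT T1 and 0% of MUT T1, which allows up to 0.0279%.

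On the stem cell side the HSC list had a median of −0.72 over 25 members (percentile 0, 0 higher and 22 lower) and the aged HSC list −0.53 over 32 (percentile 0, 14 lower). Mecom, a transcription factor gene needed for HSC upkeep (chromosome 3, 29951296 to 30548008), was at 271 CPM (268 to 274) against 618 (613 to 623), Hlf at 275 (272 to 278) against 456 (452 to 460) and Procr at 9.37 (8.83 to 9.93) against 18.8 (18.0 to 19.6). Among the genes with the lowest ratios in WT were the potassium channel gene Kcnb2 (6.26-fold lower), Il1rapl2 (3.81-fold), Taf1c, which encodes a cofactor of RNA polymerase I (3.49-fold), Sox6, a transcription factor gene that acts with Bcl11a on globin genes (3.02-fold), Clnk (2.95-fold) and Npas3 (2.76-fold). Megakaryocyte genes had a median of −0.70 over 15 (8 lower), with the platelet factor gene Pf4 at 132 against 305 CPM, and erythroid genes −0.26 over 15. The lymphoid list lay at −0.13 over 11 (percentile 8.66), with Flt3 at 121 against 151 CPM and Dntt at 87.2 against 117 CPM.

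Within HSC/MPP-like cells the HSC list had a median of −0.28 over 26 members (percentile 0) in WT T1 against MUT T1. The 2 clusters of the class were mixed differently, as cluster 3, which had 10 of the 13 HSC/MPP markers against 4 in cluster 2, was 34.8% of the class in WT T1 and 47.9% in MUT T1. Taken by cluster, which was chosen after the values were seen, the HSC median was −0.25 in cluster 2 (percentile 0, 1 higher and 0 lower) and 0.0094 in cluster 3. The aged HSC list had a median of −0.18 over 34 in the class (percentile 0, 5 lower), but 0.020 in cluster 2 and 0.062 in cluster 3. Among its members were Sbspon at 8.54 against 22.9 CPM and Gpr183 at 17.0 against 34.4 CPM. Many HSC list members also define the class. Hlf was at 757 CPM (739 to 775) against 795 (784 to 807), Mecom at 908 (889 to 928) against 1216 (1201 to 1230), Cd34 at 190 (182 to 199) against 186 (180 to 192), and Ly6a was 2.12-fold higher in WT. Elane, the neutrophil elastase gene, was at 92.9 CPM against 17.8, S100a8 at 24.8 against 2.81, Ctsg at 47.1 against 13.6, Ly6c2 at 21.99 against 2.72, the class II antigen presentation gene H2-Eb1 at 64.68 against 15 and Mid1 at 51.7 against 11.1. Lowest by ratio were Kcnb2 (3.54-fold), Taf1c (3.50-fold), Rbpms2 (3.22-fold), Fcer1g (8.33 CPM against 36.3), Hormad2 (2.65-fold) and Il1rapl2 (2.55-fold). Elane and S100a8 stood higher in other classes of WT T1 as well, at 126 against 23.7 CPM and 28.4 against 1.26 CPM in erythroid progenitor-like cells, which do not normally make them.

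The MHC class II and antigen presentation list had a median of 0.44 over 15 members (percentile 100, 5 higher), with Cd74 at 59.3 against 19.4 CPM and H2-Eb1 at 53.8 against 14.5 CPM. S phase genes had a median of 0.22 over 34 and G2 and M phase genes 0.21 over 46, both at percentile 100 with 0 members past 1.5-fold, and Mki67 was at 346 against 317 CPM and Cdk6 at 1244 against 1120 CPM. The interferon response list stood at 0.17 over 26, Myc and ribosome biogenesis at 0.16, oxidative phosphorylation at 0.15, unfolded protein response at 0.13 and glycolysis at 0.12. Medians between −0.07 and 0.02 were found for the Fc gamma receptor, NF-kB, immediate early, cell cycle inhibitor, p53, apoptosis, cholesterol, Bcl11a partner, mitochondrial and ribosomal lists. Fcgr2b was at 40.2 against 19.8 CPM, and Cdkn1c, a brake on the cell cycle in HSCs, at 3.87 against 8.60 CPM.

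The share of HSC/MPP-like cells in WT T1 depends on where the class ends. Kcnb2, Il1rapl2, Clnk and Vldlr lead its clusters 2 and 3 and also differed between the libraries, but whether they shift its bounds was not tested. Cluster 1, which had 11 of the 13 HSC/MPP markers but was led by Cd74 and H2-Aa and stayed outside the class, was 6.98% of WT T1, 13.3% of WT T2, 11.1% of MUT T1 and 11.5% of MUT T2. Cluster 16, led by Pde3b and Pgr and also outside the class, was 8.13% of WT T1 and 0% of MUT T1, which allows up to 0.0279%. It held Hlf at 660 CPM and Mecom at 468, against 309 and 322 CPM in the WT T1 cells outside clusters 14 and 16. Both levels lay below those of the HSC/MPP-like cells of WT T1 given above, Mecom by more. Of other class markers, Cd34 was at 86.7 against 173 CPM in the cells outside, and Procr at 19.3 against 10.9. With cluster 16 counted, an alternative chosen after the values were seen, the shares were 17.2% and 22.8%, with a log2 ratio of −0.40 (−0.48 to −0.32), and the aged HSC median was −0.57. The aged HSC median within the class moved to 0.021 at Leiden resolution 2 and to 0.022 when clustering left out cell cycle and immediate early genes.

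**Figure D3:**
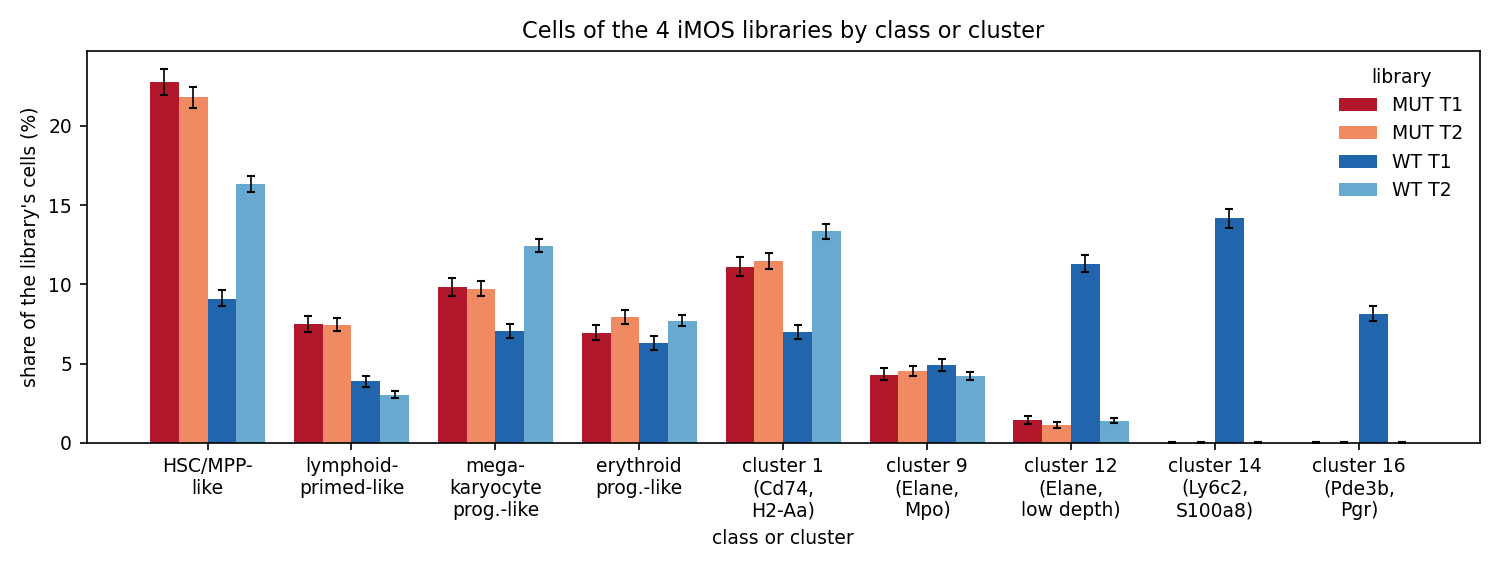
Share of cells, in percent, of 4 named classes and 5 clusters in the 4 iMOS libraries, with exact Clopper-Pearson 95% intervals for counting error. HSC/MPP-like cells made up 9.11% of WT T1, 16.3% of WT T2, 22.8% of MUT T1 and 21.8% of MUT T2, and clusters 12, 14 and 16 made up 11.3%, 14.2% and 8.13% of WT T1.

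In T2 cells WT and MUT differed by less than in T1 in the HSC/MPP-like share and in Bcl11a, but by more in the lymphoid-primed-like share. HSC/MPP-like cells made up 16.3% (15.8 to 16.8) of WT T2 and 21.8% (21.2 to 22.5) of MUT T2, 1.33-fold fewer, with a log2 ratio of −0.42 (−0.48 to −0.35). Lymphoid-primed-like cells were 3.04% against 7.44%, a log2 ratio of −1.29, where T1 had 3.88% against 7.49%, a log2 ratio of −0.95. The lymphoid list had a median of −0.36 over 10 members in T2 (percentile 0, 3 lower). Cluster 8, led by Cenpf and Nusap1 and kept out of the lymphoid-primed class by a rule set after the clusters were seen, was 4.29% of WT T2, 5.83% of MUT T2, 5.10% of WT T1 and 5.36% of MUT T1. Of 15 antigen presentation genes 5 were higher in WT by 1.5-fold, with H2-Eb1 at 64.8 CPM (63.6 to 66.1) against 16.2 (15.5 to 16.9). Bcl11a was at 376.5 against 408.1 CPM, a log2 ratio of −0.11 (−0.13 to −0.10).

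Grm8 had the highest ratio in WT T2, at 20.3 against 0.45 CPM (4.64-fold). It was followed by H2-Eb1 (3.29-fold), Mid1, a microtubule-bound ubiquitin ligase gene on the X chromosome (3.25-fold), the invariant chain gene Cd74 (3.04-fold), H2-Aa (2.97-fold) and Ncam2 (2.19-fold). The MHC class II list had a median of 0.35 over 15 members and the interferon response list 0.30 over 26 (2 higher), both at percentile 100, with the interferon signal transducer Stat1 at 96.2 against 55.1 CPM and the antiviral gene Bst2 at 91.0 against 57.8 CPM. Lowest by ratio were Taf1c (3.43-fold), the peptide transporter gene Slc15a2 (2.64-fold), Jchain, which links antibody subunits (2.08-fold), Dntt (1.99-fold), Lsm3 (1.93-fold) and Polr2l (1.87-fold). Ighm, the IgM heavy chain gene, was at 13.98 against 52.6 CPM and Flt3, a receptor of lymphoid-primed progenitors, at 98.95 against 149.8 CPM.

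The stem cell lists lay near 0 over all T2 cells. HSC genes had a median of −0.04 over 25 (percentile 8.72) and aged HSC genes 0.10 over 32 (percentile 100, 0 past 1.5-fold). Hlf was at 385 against 444 CPM, Mecom at 516 against 570, Procr at 17.3 against 18.2 and Cd34 at 171 against 189. Megakaryocyte genes had a median of 0.14 over 15, where megakaryocyte progenitor-like cells made up 12.5% of WT and 9.72% of MUT. Monocyte and dendritic genes stood at 0.15 over 18 with 5 higher, and H2-Eb1, H2-Aa, Cd74 and H2-Ab1 among these are also class II genes, while the neutrophil progenitor list lay at 0.01 and the neutrophil progenitor-like share at 5.61% against 5.65%. The basophil list lay at 0.12 and the erythroid list at −0.02. Bcl11a partners and reported targets had a median of −0.11 over 19 (percentile 0.07, 2 lower), with Sox6 at 34.0 against 66.0 CPM. Myc and ribosome biogenesis, oxidative phosphorylation and unfolded protein response genes stood at 0.13, 0.10 and 0.07, and S phase, G2 and M phase, cell cycle inhibitor and p53 genes between −0.06 and 0.02. Immediate early and Fc gamma receptor genes were both at −0.08. The ribosomal list had a median of 0.02, with 11 of its 81 members lower by 1.5-fold, such as Rps29 (1986 against 4061 CPM) and Rpl35 (549 against 1113 CPM).

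HSC/MPP-like cells of WT T2 had H2-Eb1 4.12-fold, Cd74 4.08-fold, Mid1 3.43-fold, H2-Aa 3.12-fold, H2-Ab1 2.43-fold and Fyb2 1.99-fold higher. Taf1c (3.12-fold), Slc15a2 (2.65-fold), Sox6 (2.16-fold), the amino acid transporter gene Slc7a8 (2.08-fold), Ntn4 (2.04-fold) and Gpr183 (1.79-fold) were lower. The aged HSC list had a median of −0.08 over 34 members (percentile 0.16, 0 higher and 1 lower), and the HSC list −0.10 over 26. The aged HSC median turned to 0.096 under the stricter filter, and the log2 ratio of HSC/MPP-like shares moved to −0.051 at Leiden resolution 0.5.

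**Figure D4:**
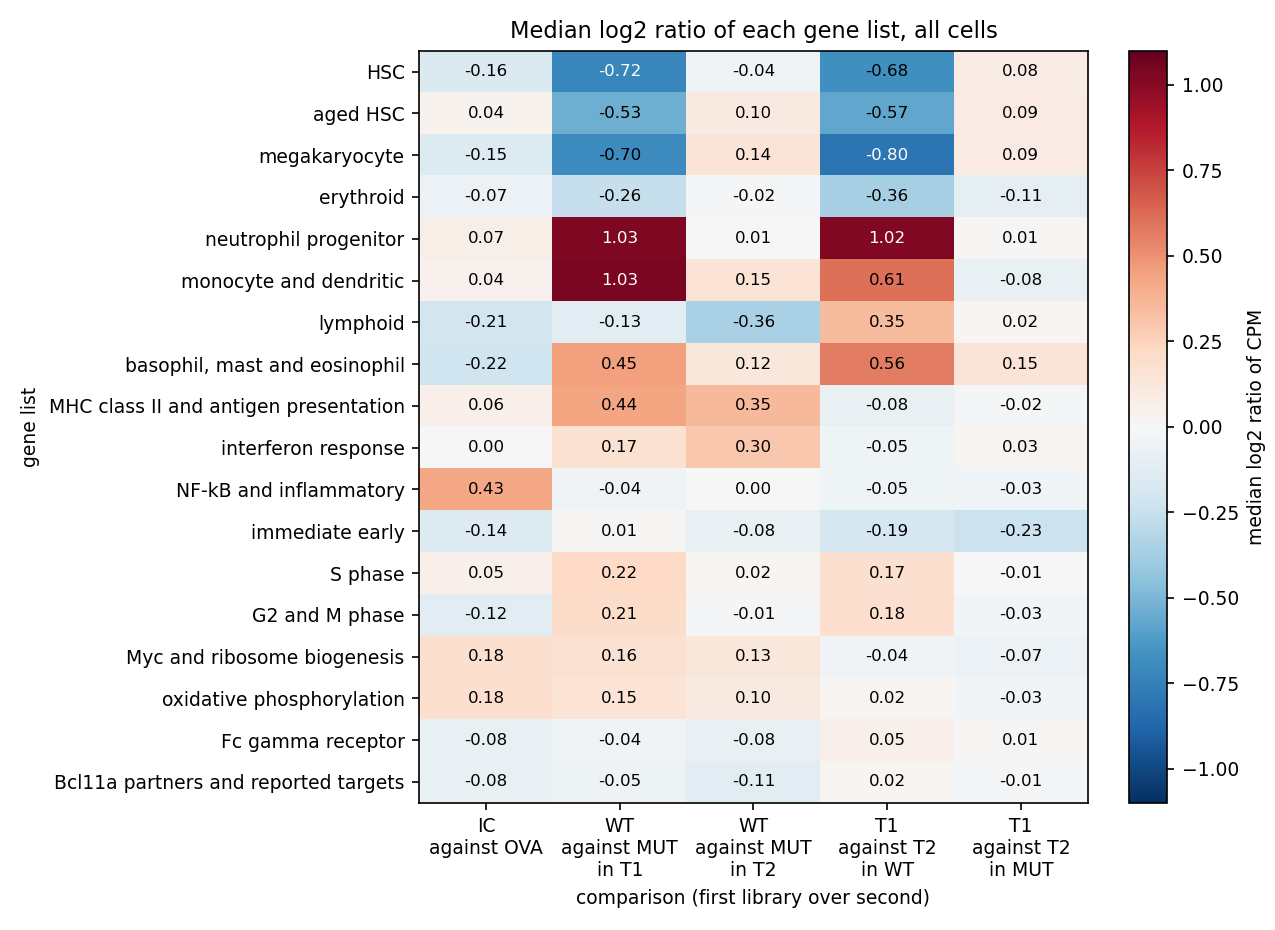
Median log2 ratio of the measured members of the described gene lists in each of the 5 comparisons, over all cells. Neutrophil progenitor and monocyte lists stand near 1 for WT against MUT in T1, where the HSC list is at −0.72, and the NF-kB list is at 0.43 for IC against OVA.

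T1 and T2 cells of the WT mice were compared to see whether the sorted fractions differ within a genotype. T1, the same library as in the comparison with MUT T1, had higher granulocyte genes, with S100a9 at 440.5 against 14.7 CPM (22.6-fold), S100a8 15.5-fold, Camp 10.2-fold, Dmkn 7.93-fold and Ngp 4.74-fold higher, and Abca9 at 20.5 against 0.64 CPM. HSC/MPP-like cells made up 9.11% of T1 and 16.3% of T2, 1.79-fold fewer, with a log2 ratio of −0.84 (−0.94 to −0.75). With cluster 16 counted the shares were 17.2% and 16.3%, and the ratio turned to 0.077 (0.00015 to 0.15). Bcl11a was at 217.7 against 376.5 CPM, a log2 ratio of −0.78 (−0.81 to −0.77), which was −0.32 both at equal cluster shares and in HSC/MPP-like cells. The globin gene Hbb-bt (3.12-fold), Il1rapl2 (2.82-fold), Fyb2 (2.63-fold), Creb5 (2.58-fold), Kcnb2 (2.53-fold) and Ppp2r2b (2.47-fold) had the lowest ratios in T1.

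Maturing neutrophil-like cells made up 0.462% of WT T1 and 0.0605% of WT T2 (7.64-fold), and held most of the Camp, Ngp and S100a9 UMIs of WT T1, at 92.5%, 94.3% and 58.2%. In these WT cells the neutrophil progenitor list had a median of 1.02 over 20 members and the monocyte and dendritic list 0.61 over 20, both at percentile 100, while HSC genes stood at −0.68 over 24, aged HSC genes at −0.57 over 32, megakaryocyte genes at −0.80 over 15 and erythroid genes at −0.36 over 15, all at percentile 0. At equal shares of 16 clusters, again with 76.18% of WT T1 cells and without clusters 14 and 22, the neutrophil and erythroid medians became −0.0050 and 0.028. The lymphoid list had a median of 0.35 over 10 (3 higher), with Ighm at 34.57 against 13.98 CPM and the lymphoid regulator Satb1 at 193 against 109 CPM, and the basophil list 0.56 over 9. S phase and G2 and M phase genes stood at 0.17 and 0.18, immediate early genes at −0.19 and the MHC class II list at −0.08. Within HSC/MPP-like cells the HSC median was −0.14 (−0.061 in cluster 2 and 0.028 in cluster 3). The aged HSC median was −0.04 in the class, but 0.048 in cluster 2 and 0.19 in cluster 3 (percentile 100, 3 higher and 0 lower). Cluster 3 was 34.8% of the class in T1 and 43.0% in T2. Fcer1g was at 8.33 CPM (6.58 to 10.4) in T1 and 43.4 (40.8 to 46.1) in T2 in HSC/MPP-like cells.

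The T1 and T2 cells of the MUT mice were close to each other. HSC/MPP-like cells made up 22.8% (21.96 to 23.6) and 21.8% (21.2 to 22.5), a log2 ratio of 0.06 (−0.01 to 0.14). The ratio depended on the clustering and on the cell filter. At Leiden resolution 2 it was 0.16 (0.07 to 0.25). Under the stricter filter, which kept the clusters, it was −0.089 (−0.27 to 0.09), an interval that holds 0 as the main one does. Lymphoid-primed-like cells were 7.49% and 7.44% and neutrophil progenitor-like cells 5.74% and 5.65%. Bcl11a was 1.06-fold higher in T1, a log2 ratio of 0.08 (0.06 to 0.10). Besides the reporter Td (0 CPM, which allows up to 0.028, against 22.9), the gene with the highest ratio was Gt(ROSA)26Sor (chromosome 6, 113067428 to 113077333, minus strand), a noncoding gene at a locus widely used for transgenes, at 23.6 CPM against 4.03.

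Among the other genes outside the mitochondrial set were Kcnb2 1.46-fold, the pseudogene Rpl10-ps3 1.45-fold, Kalrn 1.41-fold, Taf1c 1.30-fold and Rab39 1.30-fold higher in T1, and Lsm3 1.66-fold, Polr2l 1.63-fold, the ATP synthase gene Atp5k 1.497-fold, Ndufb1-ps 1.46-fold and Patl2 1.46-fold lower. Immediate early genes had a median of −0.23 over 19 members (percentile 0, 0 past 1.5-fold), with Fosb at 21.3 against 30.7 CPM, and −0.30 within HSC/MPP-like cells. HSC, aged HSC and megakaryocyte genes stood at 0.08, 0.09 and 0.09, basophil genes at 0.15, erythroid genes at −0.11, monocyte genes at −0.08, and stromal and endothelial genes at 0.06 over 5. The mitochondrially encoded gene mt-Nd4l was at 52.4 against 136 CPM, 2.45-fold lower in T1.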

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

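The tests of cluster mix, of depth and of the animals for Bcl11a, and those of a library-wide shift and of the sort gate for the clusters of WT T1, were chosen after the result was seen. In HSC/MPP-like cells the log2 ratio of WT to MUT for Ppp2r2b, a regulatory subunit of a phosphatase, was −0.6238 in T1 and 0.8359 in T2, so the 2 fractions went opposite ways past 1.5-fold. The difference between them was not tested, since each group is 1 library. It was the sole gene with such opposite ratios when the expression floor was asked of both comparisons, and that form of the floor was chosen after 3 forms had been looked at.

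Bcl11a was lower in WT than in MUT in T1 by a log2 ratio of −0.97. At equal shares of 16 clusters the ratio was −0.4867, so the mix of clusters was not its whole cause. These clusters hold 76.18% of WT T1 cells and leave out clusters 14 and 16. With each cell thinned to 2000 UMIs the ratio was −0.8893. Thinning keeps the expected fraction of Bcl11a in each cell, so it shows only that the weight of deep cells was not the whole cause. Other effects of depth were not tested. A difference of the animals or of the T1 sort stays open, with −0.1147 in T2, because every group is 1 library.

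Clusters 14 and 16 held 22.29% of the cells of WT T1 and almost none of the other iMOS libraries. Doublets stay open. Of these cells 6.22% (5.367 to 7.162) were among the 6% with the highest scores. The caller found almost no doublets in this library and was taken as not having worked, so its scores cannot decide. The median depth was 12950 UMIs in cluster 14 and 6618 in cluster 16, against 8161 over all cells of WT T1. S100a8 in erythroid progenitor-like cells was at 0.01771 of its level in cluster 14 (28.39 against 1604 CPM). Free neutrophil RNA at that level would thus be a small part of the S100a8 of cluster 14. The value does not test cluster 16, where S100a8 was at 29.17 CPM. Nor does it tell whether free RNA raised S100a8 in the other classes of WT T1. A shift of the library cannot be told apart, since the shares of a library are tied to each other. With 22.29% of the cells in clusters 14 and 16, its other 15 large clusters could not all fall to the bound set for a shift. The shares of these 15 ran from 0.3694 (cluster 0) to 10.1 (cluster 12) of the lowest share elsewhere. HSC/MPP-like cells stood at 0.5575 and erythroid and megakaryocyte progenitor-like cells at 0.7935. A wider sort gate or another condition of this library cannot be told apart from WT T1 itself, since the labels give no gate per library.

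Of 6617 genes, 295 passed 1.5-fold between WT and MUT in T1 and 50 in T2. In both fractions 30 passed in the same direction, 21 of them higher in WT, and 0 in opposite directions. At equal cluster shares the median of these 30 in T1 was 0.7948 against 0.9393 before, with 24 still past 1.5-fold. These shares cover 76.18% of WT T1 cells and leave out clusters 14 and 16. Cluster mix was thus not the whole cause in the clusters kept, though picking the genes in the same counts favours a large remainder. Their median absolute ratio between T1 and T2 in MUT was 0.153. Chromosome segments that differ between the animals stay open: 7.692% of 26 genes had another of them within 5 Mb, at percentile 35.18 of random sets. This lay below the bound of the 50th percentile set beforehand, but it equals the random median of 7.692% and lies inside the random range of 0 to 30.77%, so it decides nothing. A difference between the WT and MUT animals may explain these genes, as a hypothesis that 1 library per group leaves untested.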

How the results depend on the processing

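The settings with the highest doublet scores removed, with the Cd74 and H2-Aa cluster or the Pde3b and Pgr cluster counted, with low-depth clusters or clusters of 1 library left out of the denominator, and with HSC/MPP-like cells in place of all cells were chosen after the result was seen. Below, share means the log2 ratio of HSC/MPP-like shares, aged the median of the aged HSC list in HSC/MPP-like cells, and the comparisons are IC to OVA, WT to MUT in T1 or T2, and T1 to T2 within WT or MUT. Of 103 alternatives of the 12 main results, 43 stayed within counting error, 53 moved with the same direction and 7 turned. Of 1868 alternatives of list medians 493 moved and 4 turned, and of 7315 alternatives of named genes 2273 moved and 1 turned. A list could count as turned only if its main median had a size of at least 0.2, and a gene only from 1.5-fold. Sign changes of smaller values are thus not among those that turned. Gene values were set against the interval of the plain ratio, without the added 5 CPM. A low gene could thus count as moved without a change in its value. Called doublets were kept for IC to OVA alone, as none had been removed from the iMOS libraries, and moved neither of its 2 main results. No filter on cells moved none of the 5 results over all cells that it was run for. The stricter filter kept the clusters of the main analysis, and the standardised values used clusters where classes had been planned, with 76.18% of the cells of WT T1, without clusters 14, 16 and 22. Thinning to 2000 UMIs left out 19.26% of WT T2 cells and 13.79% of WT T1 cells. The cause was not tested for any value below, apart from settings that define it, such as another population or denominator.

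The stricter filter gave shares of 0.3856 for IC to OVA, −0.9006 in T1, −0.1396 in T2 and −0.08943 within MUT, which turned, and aged −0.2514 in T1 and 0.09557 in T2, which turned. Leiden resolution 0.5 gave shares of −1.11 in T1, −0.05137 in T2 and −0.9993 within WT, and aged −0.2058 in T2. At Leiden resolution 2 the shares were −0.3596 for IC to OVA, which turned, −1.767 in T1, −1.235 within WT and 0.1623 within MUT, and aged in T1 turned to 0.02093. Clustering without cell cycle and immediate early genes gave shares of 0.02135, −1.795 in T1, −0.3217 in T2, −1.325 within WT and 0.148 within MUT, and aged in T1 turned to 0.02234. With the 6% highest doublet scores removed the shares were 0.2938, −0.9948 in T1, −0.1423 in T2 and −0.03987 within MUT, which turned, and aged −0.1178 in T1 and −0.01048 in T2. Without low-depth clusters the shares were −0.276 in T2 and −0.9548 within WT. With the Cd74 and H2-Aa cluster counted they were −1.073 in T1 and −0.1646 in T2, and without clusters of 1 library −0.9574 in T1 and −0.4793 within WT. With the WT T1 cluster led by Pde3b and Pgr counted they were −0.4003 in T1 and 0.07727 within WT, which turned, and aged was −0.5744 in T1.

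The NF-kB median for IC to OVA was 0.476 with totals free of mitochondrial, ribosomal protein and haemoglobin genes, 0.4881 with pseudocount 1, 0.3081 at equal cluster shares and 0.5416 in HSC/MPP-like cells. TMM gave Bcl11a −0.9435 in T1 and −0.7653 within WT, and aged −0.2289 in T1. The mean of per-cell CPM gave Bcl11a −0.9235 in T1, −0.1443 in T2, −0.7164 within WT and 0.06273 within MUT, and aged −0.2371 and −0.116 in T1 and T2. Thinning gave Bcl11a −0.8893 in T1, −0.145 in T2 and −0.6768 within WT, and aged −0.1126 in T2. At equal cluster shares Bcl11a was −0.4867 in T1, −0.3237 within WT and 0.0521 within MUT, and in HSC/MPP-like cells −0.5014 in T1, −0.08151 in T2, −0.32 within WT and 0.09989 within MUT. Among the lists, the neutrophil progenitor median turned to −0.006849 in T1 and −0.005024 within WT and the erythroid median within WT to 0.02769, all at equal cluster shares, and the basophil, mast and eosinophil median in T1 turned to −0.01071 with no expression floor. Among named genes, Jchain in T1 turned to 1.02 at equal cluster shares.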

Other observations

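No test in this part was planned, and the genes of the 2 clusters of WT T1 were chosen after their values were seen. In monocyte progenitor-like cells of the culture the NF-kB list had a median log2 ratio of IC to OVA of 0.53 over 26 members, with 12 higher by 1.5-fold and 0 lower. Ptgs2 was at 101 CPM (95.8 to 106) in IC and 15.1 (13.5 to 16.9) in OVA, the iron-binding defence gene Lcn2 at 39.4 (36.2 to 42.9) and 4.46 (3.58 to 5.48), and Hmox1 at 309 and 129 CPM. The stress gene Trib3 was at 52.1 against 16.4 CPM and the stress cytokine gene Gdf15 at 85.5 against 28.7 CPM, while Irf8 was at 421 against 743 CPM. Neutrophil progenitor-like cells had Myc and ribosome biogenesis genes at a median of 0.42 over 32 and S phase genes at 0.40 over 30. They held Mt2 at 60.1 against 6.56 CPM and Elane at 3.90 against 25.3 CPM. Elane is itself a marker of the class, so its low level in both libraries weakens the class name. In both classes different clusters held the cells of IC and of OVA. Lymphoid-primed-like cells had Jchain at 251 CPM (234 to 268) in IC and 0.35 (0.043 to 1.28) in OVA, and Rag2, a gene of antigen receptor assembly, at 16.3 against 41.7 CPM.

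The interferon response list had a median above 0 for WT to MUT, at percentile 100, in each of the 5 iMOS classes described, with 0 members lower by 1.5-fold. In erythroid progenitor-like cells it was 0.57 in T1 and 0.65 in T2, with 10 and 14 of 21 members higher by 1.5-fold. Fewer members passed that size elsewhere. The median was 0.35 (3 of 23 higher) and 0.42 (4 of 23) in megakaryocyte progenitor-like cells, 0.49 (7 of 22) and 0.37 (3 of 21) in neutrophil progenitor-like cells, 0.25 (2 of 28) and 0.36 (5 of 29) in lymphoid-primed-like cells and 0.25 (1 of 28) and 0.31 (2 of 28) in HSC/MPP-like cells. For T1 to T2 in MUT the immediate early list had medians of −0.31 in erythroid (2 of 15 lower), −0.33 in megakaryocyte (2 of 18) and −0.40 in lymphoid-primed-like cells (1 of 20), all at percentile 0. Megakaryocyte progenitor-like cells of WT T1 held more mast cell transcripts than those of WT T2, with Cpa3 at 171 CPM (163 to 179) against 57.7 (54.8 to 60.8) and the interleukin 33 receptor gene Il1rl1 at 27.1 against 7.23 CPM.

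The 2 clusters found in WT T1 had distinct transcripts. Cluster 14, with 1838 cells, held Elane at 8167 CPM, S100a8 at 1604, Ly6c2 at 1316 and Bcl11a at 36.0, against 1243, 434, 147 and 267 CPM in the library's cells outside both clusters. The granule gene Camp was at 5.91 against 123 CPM. The cells outside both clusters include cluster 22, whose 60 cells held 92.5% of the Camp and 39% of the S100a8 UMIs of WT T1. The outside levels of these genes thus rest in large part on cluster 22. They do not show how cluster 14 compares with the remaining cells. Cluster 16, with 1056 cells, held the HSC genes Hlf at 660 CPM and Mecom at 468. The cells outside both clusters held them at 309 and 322 CPM, and the HSC/MPP-like cells of WT T1 higher than cluster 16. Pgr was at 503 CPM, Hmga2, a fetal stem cell regulator, at 394, and the proliferation gene Mki67 at 63.2. The cells outside both held these at 85.1, 107 and 350 CPM. GFP was at 10.1 CPM in cluster 14, 6.21 in cluster 16 and 3.90 in the others.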
